A study of Mus musculus with 16 samples.

How the data were processed

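Small RNA libraries of splenic cDC1s were measured in 16 samples, 4 in each of 4 groups: Xbp1-deficient, Ire1a and Xbp1 compound-deficient, and the wild type of each line. Per the labels' protocols, 5000 to 50000 cells per sample were sorted into Qiazol, RNA was extracted with a miRNeasy Micro kit, libraries were made with the TruSeq small RNA kit and size selected on a Pippin Prep device. Cell numbers of single samples and molecular identifiers are not given in the sources used here, so counts may include PCR copies, and intervals do not separate these from molecules. Groups and replicate numbers were taken from the sample descriptions, whose prefix gives the line of a wild-type sample. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these samples, which may be technical.

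The submitters' processing notes name cutadapt 1.8.1, FastQC 0.11.3, Bowtie 1.1.2 and limma 3.42.2 and the builds GRCm38 and mm10, without roles or order. The authors deposited raw counts, whole numbers of reads for 853 mature microRNAs named by miRBase identifiers, of which 45 are at 0 in every library. The microRNA release, the treatment of reads that match several microRNAs and the number of mismatches allowed are not given in the sources used here, so microRNAs of near-identical sequence may share reads. The authors also deposited log2 values for 473 microRNAs. From the values, each equals the log2 CPM of the count plus 0.5 over the TMM-scaled library size plus 1, with a constant per library that matched a recomputed TMM constant to within 1.47e-15. The microRNAs in that table had at least 1 CPM in at least 4 libraries, those left out in at most 3, and the latter held at most 0.0337% of the counts of a library. Both tables have 1 column per sample and none was pooled.

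The main test was edgeR 4.0.16 in R 4.3.3 on the raw counts: TMM scaling, filterByExpr by group with its default count minimum of 10, 1 quasi-likelihood fit of all 16 libraries with 4 group means and no replicate block, and two-sided F tests. The Benjamini-Hochberg adjusted p had to lie under 0.05. The filter left 255 microRNAs, which held at least 99.9% of the counts of each library, and 598 were not tested. The common biological coefficient of variation was 31.2%. There were 5 comparisons: each deficient genotype against the wild type of its line, the difference of these changes, the deficient genotypes against each other and the wild types against each other. Standard errors were the size of the log2 fold change over the square root of F, and 95% intervals used the fit's degrees of freedom. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 1. Measures of whole libraries were compared with exact two-sided permutation tests, 24 in all. Similarity of the lines' changes was tested on mean log2 CPM differences over every relabeling of the libraries within both lines. Counts of samples of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 15.7, so no library was counted as deposited more than once; this does not tell separate mice from separate preparations of 1 RNA.

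The steps were tested on simulated data: 10 runs of counts drawn from the real means and library sizes, with 200 of all 853 microRNAs changed in each. About 245 of the 853 passed the filter, so only part of the changed microRNAs were tested. For Xbp1-deficient against wild type, 20.4%, 46.4% and 86.4% of tested changes of 1.5-fold, 2-fold and 4-fold were recovered, and 3.54% of calls were false. For compound-deficient against wild type these were 21.7%, 50.8% and 80.1%, with 2.36% false. For the difference of the changes they were 6%, 29.0% and 65.3%, with 5.45% false, and for the deficient genotypes against each other 21.5%, 45.5% and 86.1%, with 5.10% false.

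The comparisons, alternatives, lists and naming rule were set before the data were examined. The naming rule took, per comparison, the 10 called microRNAs of smallest p in each direction, filled up to 10 where fewer passed, plus members of the lists. It was reduced to the 2 of smallest p in each direction, without the filling, because the files do not pair identifiers with names; MIMAT0031395 and MIMAT0003151 were named in addition, after their values were seen. For the same reason 19 lists (regulated IRE1-dependent decay substrates, unfolded protein response, microRNA families and clusters, dendritic cell activation and markers of other cell types) matched 0 microRNAs and were not tested: 9 reference tables were searched and 0 of the 853 identifiers had a name in them. The alternatives were DESeq2 size factors, total counts alone or upper-quartile scaling in edgeR, no filter, a filter of 10 CPM in 4 libraries, DESeq2 1.42.0, limma 3.58.1 with voom weights, limma on the authors' deposited log2 values, a fit of the compared groups alone, thinning to the smallest total, all 8 wild-type libraries as control, the replicate number as a block and leaving out each library in turn. A depth covariate, and a fit without the shallowest library of both compound-line groups (replicate 4 in each), were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.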

Results

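Mature microRNAs were counted in small RNA libraries of conventional type 1 dendritic cells (cDC1s), the dendritic cell subset specialised in cross-presenting antigen, sorted from mouse spleen. The 16 libraries formed 4 groups of 4: Xbp1-deficient cells, cells deficient in both Ire1a and Xbp1 (compound-deficient), and a wild-type group for each of these lines. IRE1 is a stress sensor of the endoplasmic reticulum whose ribonuclease splices the mRNA of the transcription factor XBP1 and can also cleave other RNAs. Loss of Xbp1 alone leaves this ribonuclease in place, and compound loss targets both, so the comparisons ask which microRNAs differ with loss of XBP1 and which with loss of IRE1 in addition. The activity of the ribonuclease in Xbp1-deficient cells was not measured, so a difference there need not come from the missing transcription factor alone. The targeted transcripts are messenger RNAs, which a table of mature microRNAs does not hold, so the genotype labels were not checked against them.

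Total microRNA counts ranged from 175165 to 1403393 per library. They averaged 825763 ± 322500 (SD, n = 4) in the Xbp1-line wild type, 1065596 ± 261195 in Xbp1-deficient cells, 518607 ± 252471 in the compound-line wild type and 524042 ± 341425 in compound-deficient cells. The shallowest library was compound-deficient replicate 4 and the deepest was Xbp1-deficient replicate 3. The number of microRNAs with at least 1 count was 394.5 ± 26.9 in the Xbp1-line wild type, 421.75 ± 9.91 in Xbp1-deficient cells, 389.25 ± 56.0 in the compound-line wild type and 363.5 ± 28.1 in compound-deficient cells. After every library was thinned to 175165 counts, these means lay between 315.5 and 331. The table names each microRNA by its miRBase identifier alone and the files do not pair identifiers with names, so microRNAs are given here by identifier and the choice of those named was limited to 2 per direction in a comparison, with values of the same microRNAs in other comparisons beside them.

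A single microRNA, MIMAT0000525, was the most abundant in each of the 16 libraries. It took 24.9% ± 3.72 of the counts (SD, n = 4) in the Xbp1-line wild type, 32.6% ± 2.96 in Xbp1-deficient cells, 22.8% ± 2.63 in the compound-line wild type and 21.8% ± 3.02 in compound-deficient cells. The 10 most abundant microRNAs of a library together took 74.5% ± 1.44 of the counts in the Xbp1-line wild type and 77.7% ± 1.11 in Xbp1-deficient cells. In the compound line this share was 73.7% ± 0.708 in the wild type and 76.2% ± 0.889 in compound-deficient cells. In both lines all 4 deficient libraries lay above all 4 wild-type libraries, with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give. After adjustment over the 24 tests of library measures the p was 0.171 in both lines, so neither difference passed. Passing would have needed most of the 24 tests to reach that smallest p. The adjusted result therefore says little about whether the shares differ.

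In Xbp1-deficient cDC1s, MIMAT0000516 fell from 10589 ± 2687 to 4540 ± 261 CPM (counts scaled to a common TMM library size; SD, n = 4), a log2 fold change of −1.22 (SE 0.15, 95% interval −1.54 to −0.90). MIMAT0000165 fell from 327 ± 36.5 to 105 ± 34.8 CPM, a log2 fold change of −1.65 (SE 0.30, interval −2.27 to −1.02). MIMAT0000539, among the abundant microRNAs, rose from 37092 ± 1754 to 59808 ± 6808 CPM, a log2 fold change of 0.69 (SE 0.16, interval 0.35 to 1.03). The adjusted p of edgeR's quasi-likelihood test was 5.52e-05, 0.0037 and 0.0190 for these 3 microRNAs. Of 255 microRNAs tested, 6 passed, 1 higher and 5 lower, with log2 fold changes between 0.45 and 1.75 in size. In all 6 the CPM values of the deficient libraries lay wholly above or wholly below those of the wild type. Being called on these same values makes that likely, so it is no separate support. Over all 255 microRNAs it held for 30, where chance gives 2.86%. The count of calls rested partly on single libraries: it was 2 without wild-type replicate 6, 3 without wild-type replicate 8 and 3 without deficient replicate 3, and DESeq2 called 18. MIMAT0000539 did not pass without wild-type replicate 6 or replicate 8, and MIMAT0000165 did not pass with all libraries thinned to the smallest total, while 2 higher and 3 lower passed with upper-quartile scaling and 2 higher and 5 lower with DESeq2 size factors.

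In compound-deficient cDC1s, MIMAT0000531 fell from 28674 ± 3733 to 16780 ± 1096 CPM (SD, n = 4), a log2 fold change of −0.77 (SE 0.11, 95% interval −0.99 to −0.55). MIMAT0000165 fell from 345 ± 181 to 96.1 ± 11.3 CPM, a log2 fold change of −1.83 (SE 0.31, interval −2.48 to −1.17). MIMAT0000539 rose from 35459 ± 5402 to 63756 ± 17852 CPM, a log2 fold change of 0.85 (SE 0.16, interval 0.51 to 1.18), and MIMAT0004324 rose from 473 ± 93.0 to 834 ± 157 CPM, a log2 fold change of 0.82 (SE 0.18, interval 0.44 to 1.20). The edgeR adjusted p was 0.000178, 0.00178, 0.00408 and 0.0112 in the same order. Of 255 microRNAs, 15 passed, 9 higher and 6 lower, with log2 fold changes between 0.50 and 1.83 in size. The ranges of the groups did not overlap for 12 of the 15, which were picked on these same values. Over all 255 microRNAs they did not overlap for 25, where chance gives 2.86%. The count was 23 without wild-type replicate 4, 9 without deficient replicate 2 and 5 without deficient replicate 3, DESeq2 called 24, and MIMAT0004324 did not pass without deficient replicate 3, in a fit of these 8 libraries alone or after thinning. The balance of directions moved with the scaling: 8 higher and 11 lower passed with total counts alone, and 3 higher and 21 lower with upper-quartile scaling.

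**Figure D1:**
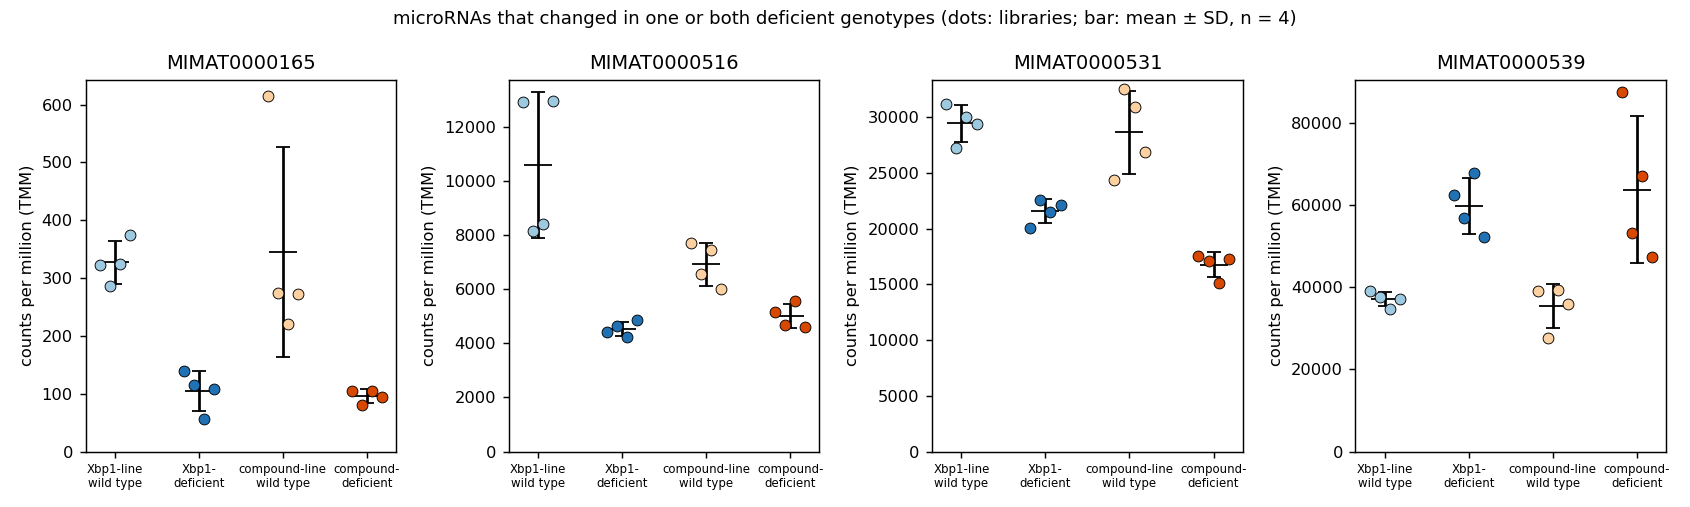
CPM (y axis, TMM-scaled) of 4 microRNAs in the 4 groups; each dot is a library and the bar is the mean with its SD (n = 4). MIMAT0000165 averaged 327 and 345 CPM in the wild-type groups against 105 and 96.1 CPM in the deficient groups, and MIMAT0000539 averaged 37092 and 35459 CPM against 59808 and 63756 CPM; for MIMAT0000516 the change passed the test in Xbp1-deficient cells, and for the other 3 in both genotypes.

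The changes of the 2 lines, which share no library, resembled each other. MIMAT0000539 passed as higher in both, and 3 microRNAs passed as lower in both, MIMAT0000165 and MIMAT0000531 among them. Independent lists of 5 and 6 lower microRNAs would share 0.118, and the one-sided Fisher's exact p was 7.19e-05. The 1 shared higher microRNA had an expectation of 0.0353 and a one-sided Fisher's exact p of 0.0353. These values treat all 255 microRNAs as independent and equally likely to be called. Calls fell mostly on abundant microRNAs in both lines, so these expectations and p-values are likely too small. All 6 microRNAs called in Xbp1-deficient cells went the same way in compound-deficient cells, with a median log2 fold change in that direction of 0.82 against 1.03 in their own comparison. Of the 15 called in compound-deficient cells, 11 went the same way in Xbp1-deficient cells, with a median of 0.43 against 0.79. For both look-ups the exact one-sided permutation p over 70 labelings of the other line was 0.0143, the smallest they can give. Across the 255 microRNAs, which are not independent replicates, the log2 fold changes correlated with Pearson's r of 0.38 and Spearman's rho of 0.30. The exact one-sided permutation p over 4900 labelings of the libraries was 0.000408 and 0.00204, and r was 0.35 without the microRNA of the largest fold in Xbp1-deficient cells.

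**Figure D2:**
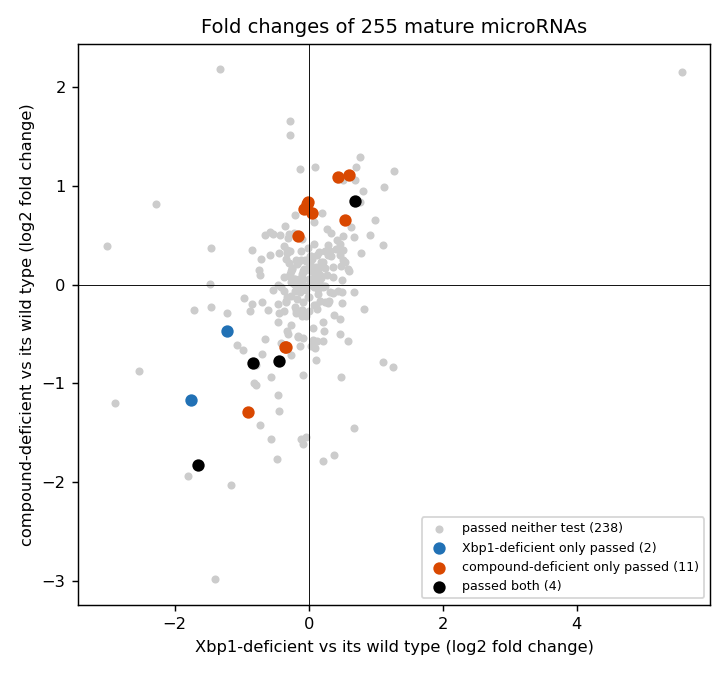
Log2 fold change in Xbp1-deficient (x axis) and compound-deficient cDC1s (y axis), each against the wild type of its line; a dot is one of 255 microRNAs, coloured by the comparison in which it passed the edgeR test. The 4 microRNAs that passed in both lie on the same side of 0 on both axes, 1 higher and 3 lower.

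Whether compound loss had another effect than loss of Xbp1 was tested directly as the difference of both changes. No microRNA passed in edgeR, where the smallest adjusted p was 0.208, 26 had an unadjusted p under 0.05 and 12.75 were expected by chance. DESeq2 called 5 and limma voom 0, and edgeR itself called 3 with upper-quartile scaling and 2 without the filter. MIMAT0004324 gave a log2 fold change of −0.03 (SE 0.18) in Xbp1-deficient and 0.82 (SE 0.18) in compound-deficient cells, and the difference of 0.85 (SE 0.26, 95% interval 0.31 to 1.38) had an edgeR adjusted p of 0.208. MIMAT0000516 gave −1.22 and −0.47, the latter at an edgeR adjusted p of 0.0815, and the difference of 0.75 (SE 0.21, interval 0.30 to 1.20) also had an adjusted p of 0.208. Most of this 0.75 lay between the wild types, where the compound line differed from the Xbp1 line by −0.61 (SE 0.15). Between the deficient genotypes the log2 difference was 0.14 (SE 0.15). For MIMAT0000531, which passed in both lines with −0.45 (adjusted p 0.0190) and −0.77, the difference was −0.32 (SE 0.15, adjusted p 0.443). For MIMAT0000165 and MIMAT0000539 the differences were −0.18 (interval −1.07 to 0.71) and 0.16 (interval −0.32 to 0.63). The depth and spread of these libraries limit this test: in simulated counts it recovered 29.0% of changes of 2-fold and 65.3% of changes of 4-fold. Many microRNAs were changed in each simulated run, and with fewer true changes the adjusted test would likely recover less.

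Compound-deficient and Xbp1-deficient cells were also compared with each other, a comparison that includes any difference between the lines. MIMAT0000210 was higher in compound-deficient cells, at 169550 ± 18346 against 111652 ± 14201 CPM (SD, n = 4), a log2 fold change of 0.60 (SE 0.13). MIMAT0003459 was higher by 3.04 (SE 0.64), at 273 ± 255 against 32.1 ± 10.8 CPM, on 44 to 117 and 23 to 43 raw counts per library. MIMAT0000525 was lower, at 223210 ± 41890 against 346950 ± 38706 CPM, a log2 fold change of −0.64 (SE 0.15), and MIMAT0000133 was lower by a log2 fold change of −0.67 (SE 0.16), at 1384 ± 297 against 2193 ± 163 CPM. The edgeR adjusted p was 0.0152 for both higher microRNAs and 0.0180 for both lower ones. In all, 19 of 255 passed, 13 higher and 6 lower. The ranges of the groups did not overlap for 14 of these 19, which were picked on these same values. Over all 255 microRNAs they did not overlap for 30, where chance gives 2.86%. Each comparison with a wild type shares its deficient libraries with this one, so a call in both is not independent support. Of the 19, 6 had also passed in compound-deficient cells against wild type and 1 in Xbp1-deficient cells against wild type. MIMAT0000210 and MIMAT0000133 were among the former, with log2 fold changes of 0.50 (adjusted p 0.0189) and −0.63 (adjusted p 0.0174) in edgeR, and their differences between the lines' changes were 0.65 (adjusted p 0.208) and −0.28 (adjusted p 0.809). MIMAT0000525 passed against wild type in neither line. Its log2 fold change was 0.05 (edgeR adjusted p 0.954) in compound-deficient and 0.49 (adjusted p 0.0883) in Xbp1-deficient cells. The difference of these changes was −0.45 (edgeR adjusted p 0.474).

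The number of calls moved with single libraries and with the depth covariate. With 1 library left out in turn the log2 fold change was 0.52 to 0.65 for MIMAT0000210, −0.82 to −0.58 for MIMAT0000133, −0.79 to −0.53 for MIMAT0000525 and 2.27 to 3.36 for MIMAT0003459. Without Xbp1-deficient replicate 1 or without replicate 2, edgeR called 0 microRNAs, with 38 and 42 at an unadjusted p under 0.05 and smallest adjusted p of 0.0751 and 0.0745. It called 1 without compound-deficient replicate 2 or without replicate 3, 9 without Xbp1-deficient replicate 3 and 7 without compound-deficient replicate 4, whereas DESeq2 on all libraries called 32. With the log2 total count as a covariate, added after the data were seen, edgeR called 3. MIMAT0000210, with a log2 fold change of 0.65 (adjusted p 0.0443), and MIMAT0004324, which rose in compound-deficient cells against wild type, were among them. MIMAT0004324 was at 1.01 (adjusted p 0.0196), against 0.84 (adjusted p 0.0152) without the covariate, whereas MIMAT0003459, at 1.16 (adjusted p 0.184), MIMAT0000525, at −0.47 (adjusted p 0.201), and MIMAT0000133, at −0.71 (adjusted p 0.0759), did not pass. MIMAT0000133 also missed the threshold with total counts alone (adjusted p 0.0676) and after thinning (adjusted p 0.0717). The split was 14 higher and 1 lower with total counts alone, 12 and 12 with DESeq2 size factors, and 4 and 22 with upper-quartile scaling.

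**Figure D3:**
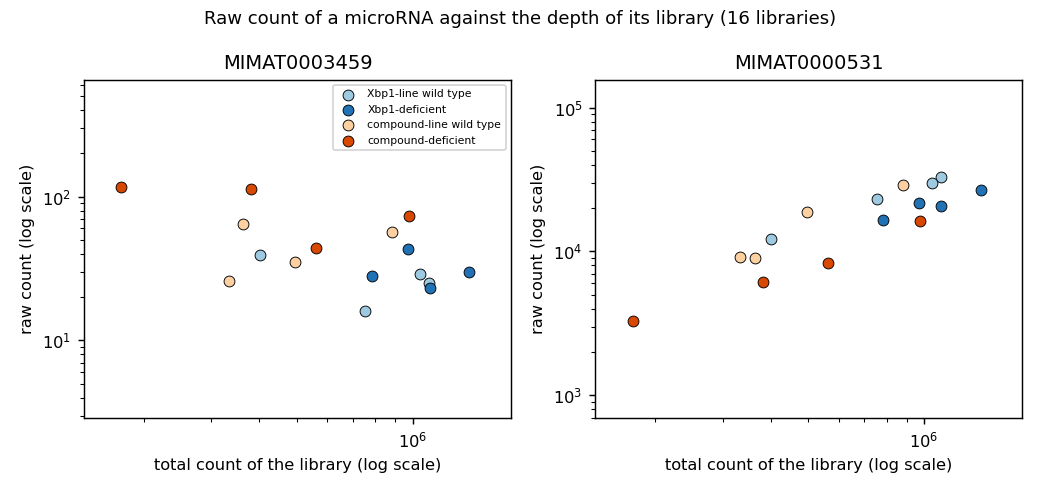
Raw count of a microRNA (y axis, log scale) against the total count of its library (x axis, log scale) for the 16 libraries, coloured by group. MIMAT0000531 rises with depth, whereas the counts of MIMAT0003459 lie between 16 and 117 across libraries of 175165 to 1403393 counts. For MIMAT0003459 they were 44 to 117 in compound-deficient and 23 to 43 in Xbp1-deficient libraries. They were 26 to 64 in the compound-line and 16 to 39 in the Xbp1-line wild type.

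Between the wild types of both lines, no microRNA passed in edgeR, where the smallest adjusted p was 0.0942 and 24 had an unadjusted p under 0.05 against 12.75 expected. DESeq2 called 4 and limma voom 0, and edgeR itself called 14 without the filter. MIMAT0000516, which shared that adjusted p, stood at 6922 ± 791 CPM (SD, n = 4) in the compound-line and 10589 ± 2687 CPM in the Xbp1-line wild type, a log2 difference of −0.61 (SE 0.15, 95% interval −0.93 to −0.29). The 2 deficient genotypes stood at 4540 ± 261 and 4994 ± 449 CPM for this microRNA, a log2 difference of 0.14 (interval −0.18 to 0.46). Among the other microRNAs named in the deficient cells, none passed between the wild types in edgeR. MIMAT0000133, MIMAT0003459 and MIMAT0000525 gave log2 differences in the direction of their difference between the deficient genotypes, at −0.38 (interval −0.71 to −0.06, adjusted p 0.366), 1.24 (interval −0.09 to 2.56) and −0.19 (interval −0.51 to 0.12), and MIMAT0000210 gave −0.05 (interval −0.32 to 0.22). The difference was 0.07 (interval −0.54 to 0.68) for MIMAT0000165, −0.06 (interval −0.40 to 0.27) for MIMAT0000539, −0.04 (interval −0.26 to 0.18) for MIMAT0000531 and −0.00 (interval −0.38 to 0.38) for MIMAT0004324. Without 1 wild-type library of the Xbp1 line, replicate 5 or replicate 6, edgeR called 1 and 2 microRNAs.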

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

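The comparison with the wild-type line difference, the test of a fixed number of reads and every fit with depth as a covariate were chosen after the data were seen. Single libraries are listed where their gap to the nearest other library of the group, taken on log2 CPM for a microRNA, exceeded, as a share of the group's range, Dixon's 95% critical value for 4 samples. Chance gives this for about 1 in 20 groups. The 5 found among 60 groups of values cannot be set against that share, since the 60 include MIMAT0003151 and MIMAT0031395, chosen after their values were seen.

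The share of the 10 most abundant microRNAs was 74.8% in compound-deficient replicate 4, the shallowest library, against 76.5% to 76.8% in the other 3, a gap of 0.840 of the range. MIMAT0004324 stood at 360 CPM in Xbp1-line wild type 4 against 506 to 521 CPM in the others, a gap of 0.924. MIMAT0000531 stood at 15152 CPM in compound-deficient replicate 3 against 17131 to 17514 CPM, a gap of 0.847. MIMAT0003459 stood at 94.5 CPM in Xbp1-line wild type 8, the shallowest library of that group, against 20.8 to 26.6 CPM, a gap of 0.841. MIMAT0003151 stood at 8735 CPM in compound-line wild type 2 against 831 to 1207 CPM in the other 3 of that group, a gap of 0.841, and its log2 fold change in compound-deficient cells of −1.78 (SE 0.53, edgeR adjusted p 0.0536) did not pass.

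The deficient genotypes differed from each other in 19 microRNAs while the wild types of their lines differed in 0 in edgeR, in 4 in DESeq2 and in 0 in limma voom, with 24 at an unadjusted p under 0.05. Without the filter, edgeR called 18 between the deficient genotypes and 14 between the wild types, so this contrast depends on the filter. A difference between the lines that their wild types also carry would need these 19 to differ between the wild types, but in the direction of each call their median log2 difference there was 0.0397 (0.00 to 0.11 with 1 library left out in turn) against 0.64 in the deficient cells, which argues against it as the whole cause. Mean library depth differed as well, but not past the threshold (exact permutation p 0.0857, adjusted p 0.294 over the 24 tests of library measures). So few libraries could hardly pass that threshold after adjustment, so a difference in depth is not excluded. With log2 total count as a covariate the median log2 fold change of the 19 was 0.59 (0.51 to 0.61 with 1 library left out in turn), against 0.64 without it. Depth thus did not account for most of that median in this fit. The 19 were picked from these same libraries, so their median cannot tell a genotype effect from chance. The calls still fell from 19 to 3, of which 2 were among the 19, as the median SE rose from 0.163 to 0.194 and some folds shrank. What stays open is loss of IRE1 in addition to XBP1, for which the difference of the lines' changes gave 0 calls in edgeR (26 at an unadjusted p under 0.05, DESeq2 5, limma voom 0), and, untested, any difference in preparation between the deficient groups. Chance in part of the 19 calls is open too, as their count was 0 to 21 with 1 library left out in turn.

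For a pair of these microRNAs depth may account for most of the difference. MIMAT0003459 and MIMAT0031395 were higher in compound-deficient cells by 3.04 and 1.98 on the log2 scale (edgeR adjusted p 0.0152 and 0.0262), and with the depth covariate by 1.16 (SE 0.42, adjusted p 0.184) and 0.27 (SE 0.24, adjusted p 0.707); the call of MIMAT0031395 was also lost without any 1 of 6 of the 8 libraries, and it differed by 1.44 (95% interval 0.38 to 2.50, adjusted p 0.269) between the wild types. Within groups, log2 CPM changed with each doubling of the total count by −1.18 (95% interval −1.57 to −0.79) and −1.13 (interval −1.37 to −0.89), near the −1 that a fixed number of reads per library would give, and their raw counts spanned 16 to 117 and 96 to 373; of all 255 microRNAs, 12 passed with a negative and 3 with a positive slope (47 at an unadjusted p under 0.05). A source of reads that does not scale with the cells' microRNAs would give such slopes, but the sources used here describe none. A fixed number of reads would also give raw counts alike in all groups. MIMAT0003459 had 44 to 117 in compound-deficient and 23 to 43 in Xbp1-deficient libraries, and MIMAT0031395 had 223 to 373 and 165 to 274. In the wild types of the compound and Xbp1 lines, MIMAT0003459 had 26 to 64 and 16 to 39. MIMAT0031395 had 161 to 239 and 96 to 143 there, so the counts also ran higher in the compound line without the deficiency. Beyond depth, neither a genotype effect nor a difference between the lines is excluded for either microRNA, and no biological explanation was tested for the trend with depth.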

How the results depend on the processing

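The fits with a depth covariate and without the shallowest compound-line libraries were chosen after the data were seen; the cause of the shifts below was not tested except where named. Counts of calls moved by over 1.5 times as follows, and no microRNA changed direction under the alternatives run for the comparison that named it (none was run for MIMAT0003151). Xbp1-deficient against wild type (6): no filter 15, DESeq2 18, only these 8 libraries 11, thinned 2, all 8 wild types as control 12, 1 library left out 2 to 9. Compound-deficient against wild type (15): upper quartile 24, DESeq2 24, only these libraries 6, thinned 8, all 8 wild types 30, 1 library left out 5 to 23. Difference of the changes (0): upper quartile 3, no filter 2, DESeq2 5, 1 library left out 0 to 0. Deficient genotypes against each other (19): DESeq2 32, the authors' log2 values 11, only these libraries 7, thinned 11, depth covariate 3, shallowest libraries left out 7, 1 library left out 0 to 21. Wild types against each other (0): no filter 14, DESeq2 4, only these libraries 2, shallowest libraries left out 1, 1 library left out 0 to 2. Thinning leaves fewer counts, and a fit of 8 libraries fewer degrees of freedom. Against TMM, the median log2 fold change over all microRNAs shifted by over 0.1 with total counts alone (−0.10 in Xbp1-deficient and −0.12 in compound-deficient cells) and with the upper quartile (0.12, −0.27, −0.39, −0.24 and 0.15 in the order above).

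MIMAT0000516 and MIMAT0000531 passed in their own comparison under every alternative run, with log2 fold changes of −1.33 to −0.95 and −1.06 to −0.71, as did MIMAT0000165 and MIMAT0000539 in compound-deficient cells. In Xbp1-deficient cells MIMAT0000165 had an adjusted p of 0.144 after thinning (6.16e-07 to 0.144 over its alternatives). MIMAT0004324 lost its call under 3 alternatives and 1 left-out library, and MIMAT0000133, MIMAT0000525, MIMAT0003459 and MIMAT0000210 under 4, 2, 1 and 0 alternatives and 4, 4, 3 and 4 left-out libraries. MIMAT0031395 lost it under 5 alternatives and 6 of 8 left-out libraries, with log2 fold changes of 0.27 to 2.35 over all of them. The difference in detected microRNAs kept its sign at 10 counts and after thinning within the Xbp1 line (27.25, 12.25 and 1.25) and the compound line (−25.75, −13.25 and −13.25), but after thinning it turned from −58.25 to 1 between the deficient genotypes and from −5.25 to 15.5 between the wild types. The exact permutation p was 0.171, 0.486 and 0.943 within the Xbp1 line and 0.457, 0.6 and 0.571 within the compound line. The kept sign therefore carries little weight.

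Replicate numbers showed no clear pairing of the samples, which so few libraries cannot exclude. Same-numbered libraries of the compound line correlated at 0.11, −0.26, 0.26 and 0.01 in their deviations from the group means. Those of the deficient genotypes correlated at 0.04, −0.07, 0.10 and 0.08. Only number 3 matched its own number best in each. In fits of the 8 compared libraries alone, a replicate block moved the calls from 6 to 4 for compound-deficient against wild-type cells and from 7 to 9 between the deficient genotypes. For Xbp1-deficient against wild type, for both wild types and for the difference of the changes no block was fitted, because the Xbp1 line's groups, and both wild types, share only number 4. The planned list tests were not run, since no identifier had a name.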

Other observations

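Calls fell mostly on abundant microRNAs. With the 255 microRNAs in 4 bins of mean abundance from lowest to highest, Xbp1-deficient cells held 0, 1, 1 and 4 calls, compound-deficient cells 0, 1, 6 and 8, and the comparison of the deficient genotypes 0, 1, 8 and 10. The median SE of the log2 fold change fell across the same bins from 0.706 to 0.150 in Xbp1-deficient and from 0.777 to 0.151 in compound-deficient cells, so changes of low-abundance microRNAs were measured less precisely. The lines' fold changes correlated across microRNAs with r of 0.57 above and 0.33 below the median abundance (exact one-sided permutation p 0.000408 for both). Spearman's rho was 0.39 above and 0.26 below it (exact one-sided permutation p 0.0273 and 0.00204).

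Other splits of the same libraries were fitted in the same way. For Xbp1-deficient against wild type, 1 of 35 splits, the real one, gave 6 calls and the highest other gave 4. For compound-deficient against wild type it was 1 of 35, with 15 calls against 8, and for the deficient genotypes 1 of 35, with 19 against 5. A share of 1 in 35 is the smallest these splits can give. It was not adjusted over the 3 counts, so chance is less likely but not excluded. For the difference of the changes, where edgeR gave 0 calls (26 at an unadjusted p under 0.05, DESeq2 5, limma voom 0), 100 of 100 splits drawn gave at least as many and the highest gave 6. For the wild types, with 0 calls in edgeR (24 at an unadjusted p under 0.05, DESeq2 4, limma voom 0), 35 of 35 did and the highest gave 1. With 0 real calls every split gives at least as many, so these counts say nothing about chance.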
